A study of Mus musculus with 12 samples.

How the data were processed

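Total RNA from 12 cultures of mouse keratinocytes was labelled with biotin by a whole-transcript kit and hybridised to Affymetrix arrays, 1 array per culture. The deposited table gives an intensity per probe set, made by the authors with RMA (background correction, quantile normalization and summary of probes) in Affymetrix Expression Console 1.3.1.187, per the submitters' processing notes. The deposited values were whole numbers from 3 to 17695 with nearly equal medians in every array. They were read from the values as RMA signals returned to a linear scale and rounded, and their log2 was taken. Any filter, and the genome build behind the probe sets, are not given in the sources used here. Rounding makes the log2 of the dimmest probe sets coarse, which the alternative with 16 added to each signal addresses.

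Of 41345 probe sets, 23521 carried 1 gene symbol in the platform annotation, 1814 carried several and 16010 carried none. Gene identifiers of 23328 single-symbol probe sets matched a mouse gene table (assembly GRCm38.p6), and the match changed 0 symbols. The platform annotation can be old, and 22 members of the gene lists were found through an older symbol. Where a gene had more than 1 probe set (1082 genes), the probe set with the highest mean log2 signal stood for it. This left 22180 genes, with no filter on signal.

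A linear model with 1 mean per group was fitted to the 12 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with no block. The 4 groups were wt sham, wt paraquat, KO sham and KO paraquat, each with 3 arrays. Tested were paraquat against sham in each genotype, KO against wt in each treatment, and the difference between the responses (KO response minus wt response). Each used limma's moderated test, 2-sided, with Benjamini-Hochberg adjustment over the 22180 genes and a threshold of 0.05 on the adjusted p. Standard errors (SE) of log2 changes come from the same fit, and SD is given between the 3 arrays of a group. Atg7 was also tested by an exact permutation test on mean log2 signal, 6 KO against 6 wt arrays.

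Gene lists were tested against all other genes with limma's camera at a preset correlation of 0.01, adjusted over 34 lists and 5 comparisons (170 tests). The estimated correlation of each list and limma's fry (with statmod 1.5.0 available) were run beside it. At the preset correlation 83 of the 170 tests passed, and with an estimated correlation 0 passed, with 38 at an unadjusted p under 0.05 and a smallest adjusted p of 0.127. Fry, which does not compare a list with other genes, passed 71. List members were counted as changed over all genes tested and adjusted over the list alone. The lists held 876 entries, of which 788 were measured. Of the 765 measured genes in any list, 21 stood in more than 1, among them 6 of the 7 genes in the list named CXCR2 ligands. That list also holds Pf4, which is not a classical CXCR2 ligand, and the name is used below for the whole list. In 21 of the 170 tests the median, the mean and camera's direction differed in sign, and 0 of these 21 passed. The lists include markers of fibroblasts, melanocytes, leukocytes and Langerhans cells, endothelium, and hair follicle, sebaceous and Merkel cells, which a keratinocyte culture could hold.

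The named genes were chosen by a rule. It takes Atg7, then in each comparison the 10 largest rises and the 10 largest falls among genes past the threshold whose arrays do not overlap between the groups (no such condition for the difference between responses). Predicted and clone-named genes, microRNA, small nucleolar, olfactory, vomeronasal and receptor-segment genes and probe sets of several genes were left out. From each list it takes up to 4 members past the threshold in order of p, or the 2 with the smallest p as values alone. The groups, comparisons, tests, lists, this rule and most alternatives were set before the data were examined. The plan assumed log2 values in the deposited table, so taking their log2 was decided after the values were read.

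Alternatives were a second quantile normalization, centring on the array median, a filter keeping genes above the median of all probe sets in at least 3 arrays, the mean over a gene's probe sets, every probe set tested, a variance trend, array weights, at least 1.5-fold change, the 6 arrays of the groups compared, the replicate number as a block, fry, and leaving out each array in turn. Added after seeing the data were 16 added before the log2, leaving out wt sham 2 and KO paraquat 3 together, and both rescalings for the gene lists. The method was tested on simulated arrays for each comparison, with 100 genes changed at 2-fold and 100 at 1.5-fold. These were drawn from genes with a mean log2 signal above the median, with independent noise and no other differences. Recovery was thus not measured for dim genes. At 2-fold the method recovered 96, 95, 93 and 98 of 100 genes in the 4 pairwise comparisons. In the difference between responses it recovered 82 of 100, and at 1.5-fold the recoveries were 69, 70, 69, 73 and 48. False calls numbered 7, 9, 7, 5 and 4. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Probe sets with no symbol or several were left out of the gene tests and counted apart.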

Results

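Gene expression was measured in 12 arrays of cultured mouse keratinocytes, the main cell type of the epidermis. The cells carried Atg7 alleles flanked by recombination sites. They either lacked the K14::Cre recombinase (wt, autophagy competent) or carried it (KO, autophagy deficient), K14 being a keratin gene of basal keratinocytes. Each genotype was sham treated or given 20 µM paraquat, a herbicide that cycles with oxygen and produces superoxide, and RNA was taken after 48 h. Each of the 4 groups held 3 arrays. The labels call them biological triplicates but do not tie arrays to animals, so each p-value measures only the spread between these samples. The median signal per array was 42 to 45, and the number of arrays limits the precision. Background was not measured. Of the 20 genes named by size in each comparison, 7 to 10 had a mean signal under 45, the highest array median, in at least 1 group, so their folds rest on levels not shown to be above background. The first principal component held 74.2% of the variance and parted paraquat from sham. The second held 12.6%, with wt sham 2 at -28.6 against -9.95 and -18.2 for the other wt sham arrays. The third held 3.03%, with KO paraquat 3 at -14.5 against -4.11 and -4.47 for the other KO paraquat arrays.

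The targeted gene was compared first, since it bears on the genotype labels. Atg7, the enzyme that activates ATG12 and the LC3 family for autophagosome formation, was lower in all 6 KO arrays (signals 96 to 148) than in all 6 wt arrays (286 to 457). In sham cultures it was 2.92-fold lower in KO (log2 -1.55 ± 0.13, SE, n = 3 arrays per group, adjusted p = 2.8e-05 in limma). Under paraquat it was 3.65-fold lower (log2 -1.87 ± 0.13, adjusted p = 4.1e-05), and from the 6 paraquat arrays alone it missed the threshold (adjusted p = 0.0512). Over both treatments the mean log2 difference was -1.71, and a 2-sided exact permutation test of 6 against 6 arrays gave p = 0.00216, the smallest p this test can give. Its relabellings were not kept within treatments, although Atg7 in wt was higher under paraquat than in sham. The probe set covers the whole transcript and may lie mostly outside the deleted part, so the remaining signal does not measure remaining protein.

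**Figure D1:**
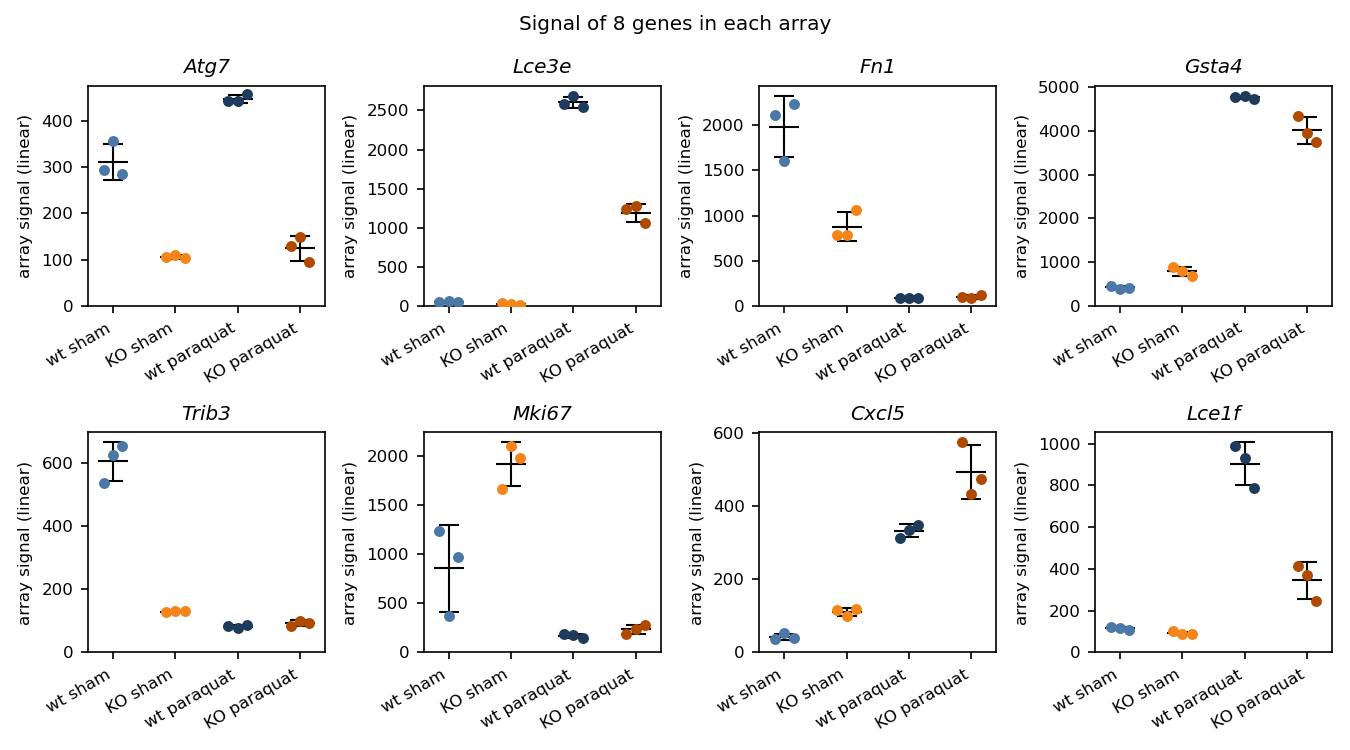
Linear array signal of 8 genes in each of the 12 arrays, by group. Points are arrays, and bars are the mean ± SD of 3 arrays. Atg7 lies at 96 to 148 in KO and 286 to 457 in wt, while Trib3 lies at 536 to 655 in wt sham and at or below 130 in every other array.

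The response of wt keratinocytes to paraquat was the next comparison. Most of the largest rises were in genes of the cornified envelope, the cross-linked protein and lipid shell of the outermost keratinocytes. Lce3f, a late cornified envelope gene, rose 56.1-fold (log2 5.81 ± 0.32, SE, n = 3 arrays per group, adjusted p = 2.59e-08), from a mean signal of 75.7 ± 53.1 (SD) to 3661 ± 226. Lce3e, Lce3a, Lce3d, Lce1e and Lce3b rose by log2 5.64, 5.60, 5.03, 5.03 and 4.60. Alox12b, a lipoxygenase of the skin lipid barrier, rose by log2 4.70. Dhrs9, a retinol dehydrogenase, rose by log2 5.65, Psca by 4.68, and Glul, which makes glutamine, by 4.55. The largest fall was in Fn1, encoding fibronectin, which was 23.3-fold lower (log2 -4.54 ± 0.17, adjusted p = 1.28e-09), with mean signals of 1984 ± 338 in sham and 84.3 ± 0.577 under paraquat. The matrix gene Postn (log2 -3.84), the contractile actin gene Acta2 (-3.63), the TGF-beta-induced matrix gene Tgfbi (-3.05) and the cytokine gene Tslp (-3.16) also fell. Further falls were in Niban1 (-3.54), the cationic amino acid transporter Slc7a3 (-3.33), the mitochondrial gluconeogenic enzyme Pck2 (-3.00), B4galnt2 (-2.96) and Depp1 (-2.95).

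Lists of the outer and of the basal keratinocyte layers moved in opposite directions in wt. Of 37 cornified envelope and barrier genes, 34 rose (35 adjusted over the list alone), with a median log2 of 1.75. The camera adjusted p was 1.65e-25, and adjusted p = 0.166 with an estimated correlation. Of 22 suprabasal differentiation genes, 14 rose and 3 fell (15 and 3 adjusted over the list alone; camera adjusted p = 1.29e-06, adjusted p = 0.202 with an estimated correlation). Members included Ivl (2.73), a precursor of the envelope, and the transcription factors Grhl3 (2.23), Ovol1 (1.96) and Elf3 (1.95). Of 12 wound and stress genes, 9 rose and 1 fell (9 and 2 adjusted over the list alone), with camera adjusted p = 3.19e-06 and adjusted p = 0.202 with an estimated correlation. They included Il1f8 (3.42), Il1f9 (3.20) and Il1f6 (2.71), members of the interleukin-36 family, and S100a9 (2.76). Of 17 basal keratinocyte genes, 9 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 0.00301, adjusted p = 0.467 with an estimated correlation). Col7a1, the anchoring fibril collagen, fell by 2.26 on the log2 scale, and the adhesion genes Itgb4, Lamb3 and Itgb1 changed by -1.20, -1.18 and -0.72. Of 26 extracellular matrix and TGF-beta genes, 15 fell and 3 rose (16 and 3 adjusted over the list alone; camera adjusted p = 1.26e-06, adjusted p = 0.166 with an estimated correlation), such as Fn1, Acta2 and Tgfbi.

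Stress and growth lists also changed in wt under paraquat. Of 31 p53 targets, 21 rose and 2 fell, also when adjusted over the list alone (median log2 0.58, camera adjusted p = 1.04e-08, adjusted p = 0.166 with an estimated correlation). Mdm2, the p53 ubiquitin ligase, rose by log2 1.65, Cd80 by 2.45, Dcxr by 1.46 and Ddit4l by 1.46. Of 28 NRF2 antioxidant targets, 17 rose and 5 fell, also when adjusted over the list alone (camera adjusted p = 7.39e-04, adjusted p = 0.255 with an estimated correlation). Gsta4, which conjugates lipid peroxidation products, rose by log2 3.50, Nqo1 by 1.92, Txnrd1 by 1.76 and the ferritin gene Fth1 by 1.14. Of 22 superoxide and peroxide enzymes, 10 rose and 4 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.0185, adjusted p = 0.388 with an estimated correlation), among them Glrx (2.07) and Gpx3 (1.24). Of the 7 genes in the CXCR2 ligand list, mostly chemokines that attract neutrophils, 5 rose, also when adjusted over the list alone (camera adjusted p = 8.43e-06, adjusted p = 0.166 with an estimated correlation). These included Cxcl3 (4.25), Cxcl5 (2.98), Cxcl2 (1.65) and Cxcl1 (1.45). Of 29 autophagy genes, 15 rose and 4 fell (16 and 5 adjusted over the list alone; camera adjusted p = 0.0168, adjusted p = 0.489 with an estimated correlation). Gabarapl2 (1.21) and Gabarap (0.78) rose, while Ulk2 (-1.10) and Map1lc3b (-1.10) fell.

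Further lists fell in wt. Of 34 targets of ATF4, the transcription factor of the integrated stress response, 29 fell and 1 rose, also when adjusted over the list alone (median log2 -1.11, camera adjusted p = 1.62e-20, adjusted p = 0.166 with an estimated correlation). Trib3 (-2.88), Pck2 (-3.00), the amino acid transporter Slc7a5 (-2.22) and the folate enzyme Mthfd2 (-1.98) had the smallest p. The mean log2 signal over this list was 9.58 in wt sham, against 8.42 in wt paraquat, 8.48 in KO sham and 8.43 in KO paraquat. The fall thus rests on a level that only the wt sham arrays had. Of 31 mitosis genes, 18 fell (22 adjusted over the list alone; camera adjusted p = 1.05e-06, adjusted p = 0.565 with an estimated correlation), among them Mki67 (-2.17), Anln (-1.70) and Ndc80 (-1.15). Wt sham 2 had a mean log2 of 6.84 over this list, against 8.07 and 7.68 in the other wt sham arrays. Without it 29 mitosis genes fell, and 10 without wt sham 1 or without wt sham 3. Of 29 DNA replication genes, 18 fell (19 adjusted over the list alone; camera adjusted p = 1.41e-05, adjusted p = 0.482 with an estimated correlation), such as Pole (-1.26) and Mcm2 (-0.88). Of 25 DNA repair genes, 15 fell and 2 rose (16 and 2 adjusted over the list alone; camera adjusted p = 8.89e-05, adjusted p = 0.359 with an estimated correlation), such as Brca2 (-1.09) and Atm (-0.81). Of 21 genes of the unfolded protein response of the endoplasmic reticulum, 10 fell and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.00955, adjusted p = 0.202 with an estimated correlation), such as Ero1a (-1.41) and Xbp1 (-1.20). Of 15 glycolysis genes, 8 fell and 1 rose (10 and 1 adjusted over the list alone; camera adjusted p = 9.44e-04, adjusted p = 0.306 with an estimated correlation), among them the glucose transporter Slc2a1 (-1.54) and Pfkp (-1.23).

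Smaller or mixed shifts filled the remaining lists in wt. Of 19 cholesterol synthesis genes, 10 rose and 1 fell (12 and 2 adjusted over the list alone; camera adjusted p = 0.00367, adjusted p = 0.575 with an estimated correlation), such as Dhcr7 (1.40). Of 26 ribosomal protein genes, 6 fell, also when adjusted over the list alone (camera adjusted p = 0.0227, adjusted p = 0.593 with an estimated correlation), such as Rpl3 (-0.79). Without wt sham 2 the camera adjusted p of the ribosomal proteins was 0.156. The other metabolic lists did not pass camera: 11 of 32 fatty acid and phospholipid genes rose and 9 fell (adjusted p = 0.812), 6 of 34 oxidative phosphorylation genes rose and 2 fell (0.489), and 9 of 25 genes of oxidised lipids and prostaglandins rose and 6 fell (0.184). Members were Agpat2 (1.49), Ndufa4 (0.97) and Ptges (2.30). Protein turnover lists were mixed, with 5 of 31 proteasome genes rising and 2 falling (0.676), 9 of 26 lysosome genes rising and 5 falling (0.956), and 5 of 17 heat shock genes rising and 4 falling (0.785). Psmc2 (-0.77), Hexa (-1.43) and Cryab (1.46) were among them. Of 9 metallothionein and metal-handling genes 3 rose and 3 fell (0.685), of 14 histone genes, 4 of them H1 linker histones, 3 rose and 3 fell (0.991), and of 29 type I interferon genes 3 rose and 4 fell (0.649). Slc40a1 (-1.21), H1f3 (1.31) and Mx1 (1.21) were members. Of 23 NF-kB and inflammation genes 7 rose and 8 fell (0.717), and of 39 senescence-associated secretory genes 13 rose and 8 fell (0.243), such as Tnfaip2 (2.18), Tlr2 (-1.44) and Igfbp2 (-2.31).

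Markers of other cell types were tested as lists in wt. Of 12 melanocyte genes 4 rose (5 adjusted over the list alone; camera adjusted p = 0.0166, adjusted p = 0.406 with an estimated correlation), such as Mlana (2.57). The mean log2 signal over the melanocyte list was 5.28 ± 0.133 (SD) in wt sham and 5.75 ± 0.113 in wt paraquat. Without wt paraquat 1 the median log2 of the cell type: melanocyte list was 0.18, against 0.29 with all arrays. The other lists did not pass camera. Among 19 fibroblast genes Pdgfra (1.5) rose and Fbln2 (-0.80) and Fbln1 (-0.64) fell (adjusted p = 0.931). Among 17 leukocyte and Langerhans genes 3 rose, such as Cd68 (1.64), and 2 fell, such as Epcam (-1.09), with adjusted p = 0.444. Of 12 endothelial genes 3 rose, such as Kdr (2.21), with adjusted p = 0.14. The mean log2 signal over the endothelial list was 5.24 ± 0.0461 (SD) in wt sham and 5.57 ± 0.0233 in wt paraquat. Fry, which asks whether members move one way without comparing them with other genes, gave adjusted p = 3.75e-04 for endothelial, 0.00102 for melanocyte, 0.00245 for leukocyte, 0.0301 for hair follicle and 0.863 for fibroblast genes. Of 18 hair follicle, sebaceous and Merkel genes 3 rose, such as Krt75 (1.90), and 3 fell, such as Krt79 (-1.25), with adjusted p = 0.532. Over all 22180 genes, 6480 changed in wt (29.2%), 3311 higher and 3169 lower. Of these, 683 rose and 471 fell by at least 2-fold. Requiring at least 1.5-fold left 2999 genes. The balance of rises and falls turned with a filter on dim genes (3249 higher, 3323 lower) and over every probe set (4010 higher, 4343 lower).

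**Figure D2:**
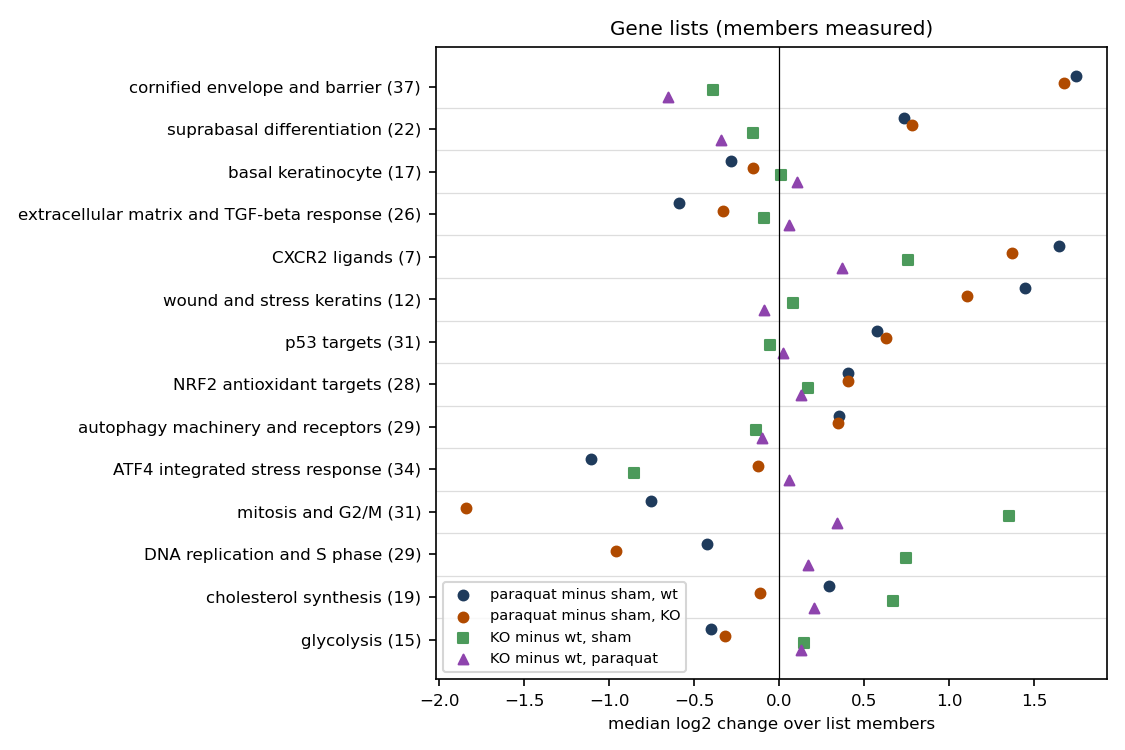
Median log2 change over the measured members of 14 gene lists (vertical axis, members in brackets) in 4 comparisons (horizontal axis, log2; circles paraquat minus sham in wt and in KO, squares and triangles KO minus wt in sham and under paraquat). The ATF4 list lies at -1.11 in wt and -0.12 in KO for paraquat, and at -0.86 for KO minus wt in sham.

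The same question was asked of the KO keratinocytes. Dhrs9 (log2 5.50) and cornified envelope genes again had the largest rises. Alox12b rose 24.5-fold (log2 4.62 ± 0.21, SE, n = 3 arrays per group, adjusted p = 2.39e-08), and Lce3e, Lce3f, Lce1e, Lce3d, Lce3b and Lce3a rose by log2 5.46, 5.43, 4.87, 4.56, 4.24 and 4.22. The envelope precursor Sprr2e rose by log2 4.27 and the calcium-binding psoriasin homologue S100a7a by 3.98. Depp1 (log2 -3.35), the chloride channel regulator Clca3a2 (-3.34), Tgfbi (-3.28) and Fn1 (-3.11) had the largest falls. Mki67, the marker of cycling cells, was 8.18-fold lower (log2 -3.03 ± 0.33, adjusted p = 1.38e-05), with mean signals of 1919 ± 223 (SD) in KO sham and 236 ± 44.0 under paraquat. Phxr4 (-2.84), the kinase gene Nuak1 (-2.70), Dipk1a (-2.60), Pi15 (-2.58) and the kinetochore gene Knl1 (-2.57) fell.

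Of the 37 cornified envelope genes 34 rose in KO, also when adjusted over the list alone (median log2 1.68, camera adjusted p = 1.68e-24, adjusted p = 0.166 with an estimated correlation). Of 22 suprabasal genes 16 rose and 3 fell (17 and 3 adjusted over the list alone; camera adjusted p = 3.9e-07, adjusted p = 0.202 with an estimated correlation), such as Ivl (2.32) and the cross-linking transglutaminase Tgm1 (2.03). Of 12 wound and stress genes 8 rose and 1 fell (10 and 1 adjusted over the list alone; camera adjusted p = 1.88e-06, adjusted p = 0.202 with an estimated correlation), such as the antimicrobial peptide gene Defb3 (3.93) and Il1f8 (3.09). Of 31 p53 targets 24 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 1.31e-12, adjusted p = 0.166 with an estimated correlation), such as Mdm2 (1.62), Sesn2 (1.25) and Trp53inp1 (1.24). Of 28 NRF2 targets 17 rose and 3 fell (17 and 4 adjusted over the list alone; camera adjusted p = 6e-05, adjusted p = 0.202 with an estimated correlation), such as Gsta4 (2.35), Txnrd1 (1.63) and Akr1b8 (1.47). Of 7 CXCR2 ligands 5 rose, also when adjusted over the list alone (camera adjusted p = 1.06e-04, adjusted p = 0.166 with an estimated correlation), such as Ppbp (2.43) and Cxcl5 (2.15). Of 29 autophagy genes 14 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 2.58e-04, adjusted p = 0.3 with an estimated correlation), such as Map1lc3a (0.87) and Atg12 (0.87).

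Cell division genes fell throughout their lists in KO. All 31 mitosis genes fell, also when adjusted over the list alone (median log2 -1.84, camera adjusted p = 2.41e-22, adjusted p = 0.249 with an estimated correlation), such as Anln (-2.24), Hmmr (-2.01) and Nek2 (-1.37). All 29 DNA replication genes fell, also when adjusted over the list alone (camera adjusted p = 1.59e-19, adjusted p = 0.19 with an estimated correlation), such as Ccne1 (-1.35) and Mcm7 (-1.26). Of 25 DNA repair genes 19 fell, also when adjusted over the list alone (camera adjusted p = 1.69e-10, adjusted p = 0.191 with an estimated correlation), such as Brca2 (-1.52) and Fancb (-1.34). Of 26 matrix genes 14 fell and 2 rose (15 and 3 adjusted over the list alone; camera adjusted p = 7.21e-05, adjusted p = 0.202 with an estimated correlation), such as Acta2 (-2.54) and Col12a1 (-2.26). Of 15 glycolysis genes 10 fell and 1 rose, also when adjusted over the list alone (camera adjusted p = 3.15e-05, adjusted p = 0.202 with an estimated correlation), such as Slc2a1 (-1.34) and Slc16a3 (-1.13). Of 34 ATF4 targets 8 rose and 10 fell (9 and 13 adjusted over the list alone), with a median log2 of -0.12 and camera adjusted p = 0.243. The median of this list (ATF4 integrated stress response) was -0.06 without KO sham 1, -0.19 without KO sham 3 and -0.20 without KO paraquat 3. Sesn2 (1.25) and Slc7a11 (1.05) rose and Atf3 (-1.31) fell. Of 19 cholesterol synthesis genes 2 rose and 6 fell (3 and 7 adjusted over the list alone; camera adjusted p = 0.192), such as Dhcr7 (0.98) and Nsdhl (-0.85). Of 12 melanocyte markers 4 rose, also when adjusted over the list alone (camera adjusted p = 0.118), such as Mlana (2.36). Fry in KO gave adjusted p = 0.00647 for melanocyte, 0.00172 for endothelial, 0.00554 for leukocyte, 0.308 for hair follicle and 0.738 for fibroblast genes. Over all genes 6017 changed in KO (27.1%), 3217 higher and 2800 lower, of which 522 rose and 424 fell by at least 2-fold. Requiring at least 1.5-fold left 2570 genes. The share of rises, 53.5%, was 63.1% with centring on the array median (3939 higher, 2299 lower), and over every probe set falls were the more numerous (3676 higher, 4362 lower).

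**Figure D3:**
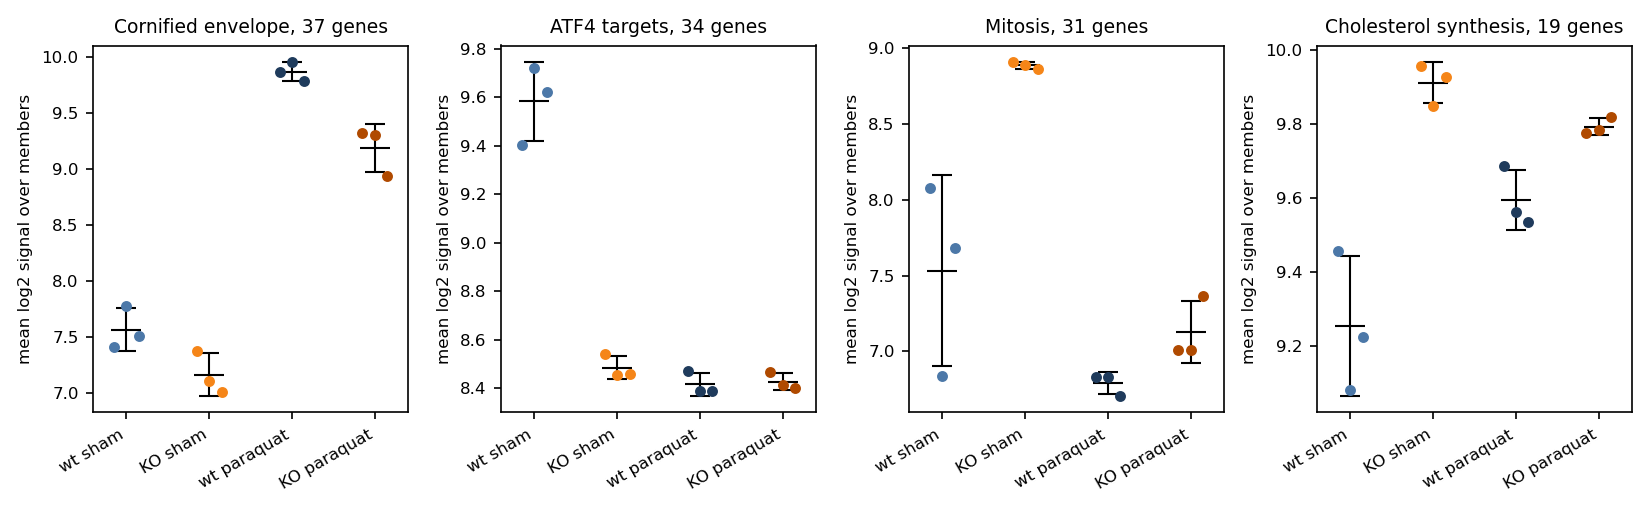
Mean log2 signal over the measured members of 4 gene lists (vertical axes, which do not start at 0) in each of the 12 arrays, by group. Points are arrays, and bars are the mean ± SD of 3 arrays. The ATF4 list lies at 9.40 to 9.72 in wt sham, and the mitosis list spans 6.84 to 8.07 in wt sham and 8.86 to 8.90 in KO sham.

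KO and wt cultures were then compared without paraquat. Niban1 was 6.18-fold lower in KO (log2 -2.63 ± 0.11, SE, n = 3 arrays per group, adjusted p = 6.44e-08), with mean signals of 898 ± 76.4 (SD) in wt and 146 ± 17.1 in KO. The amino acid transporter Slc7a3 (log2 -3.37), at a dim 37 ± 2.65 in KO, and the mitochondrial thioesterase Acot2 (-3.25) had the largest falls. The mitochondrial folate enzyme Aldh1l2 (-2.51), Pck2 (-2.20) and the pseudokinase gene Trib3 (-2.22) also fell. B4galnt2 (-2.91), Fam171b (-2.65), the carbonic anhydrase Car6 (-2.51) and Reep6 (-2.31) were also lower. The largest rises were in the cysteine protease inhibitors Csta3 (2.90) and Stfa3 (2.74) and the chemokine Cxcl3 (2.56). In wt sham the mean signals of Csta3 (31.7 ± 8.51, SD) and Cxcl3 (24.7 ± 9.29) lay below the array medians. So did those of Ccr3 (25.3) and Clca3a2 (36.7) in wt sham, and of B4galnt2 (31.3), Fam171b (20) and Car6 (22.3) in KO sham. Car6 also varied widely within wt sham (152 ± 112). The cytokine gene Il24, at 279 ± 15.5 in wt, was 3.85-fold higher (log2 1.95 ± 0.12, adjusted p = 1.04e-06). Ccr3 (2.37), Clca3a2 (2.31) and Steap4 (2.11) rose, and so did the mitotic genes Depdc1a (2.22), Shcbp1 (2.02) and Kif20a (1.88).

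Of 34 ATF4 targets 33 were lower in KO sham, also when adjusted over the list alone (median log2 -0.86, camera adjusted p = 4.53e-47, adjusted p = 0.127 with an estimated correlation), such as Slc7a5 (-1.59). The mean log2 signal over this list was 9.58 ± 0.162 (SD) in wt sham and 8.48 ± 0.0479 in KO sham, and the 9 arrays outside wt sham lay at 8.39 to 8.54. Of 29 autophagy genes 7 fell (9 adjusted over the list alone; camera adjusted p = 4.3e-04, adjusted p = 0.306 with an estimated correlation). They included the autophagy receptor Sqstm1 (-1.17), the kinase Ulk2 (-0.68), Calcoco1 (-0.66) and Atg7 itself. The fall of Atg7 was set by the knockout, and the list was not tested without Atg7. Of 26 lysosome genes 6 fell (7 adjusted over the list alone; camera adjusted p = 1.74e-04, adjusted p = 0.202 with an estimated correlation), such as Hexa (-0.78) and Ctsl (-0.52). Without wt sham 2 the lysosome count was 1, and without KO sham 1 or 2 it was 2. Of 28 NRF2 targets 6 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 0.00314, adjusted p = 0.31 with an estimated correlation). Gsta4 (0.89) and Nqo1 (0.83) rose, and the cystine transporter Slc7a11 (-1.35) and Abcc4 (-0.68) fell. Without KO sham 2, 3 NRF2 targets rose. Of 31 p53 targets 6 rose and 8 fell (7 and 9 adjusted over the list alone; camera adjusted p = 0.491), such as Ckap2 (1.39) and Sesn2 (-1.21). Of the p53 targets 3 rose without wt sham 2, KO sham 1 or KO sham 2, and 5 fell without wt sham 2, KO sham 2 or KO sham 3.

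All 31 mitosis genes were higher in KO sham, also when adjusted over the list alone (median log2 1.35, camera adjusted p = 4.12e-31, adjusted p = 0.202 with an estimated correlation), such as Hmmr (1.73), Ndc80 (1.54) and Nusap1 (1.33). The array wt sham 2, which stood apart, had the lowest mitosis mean. Without it all 31 were called, with a median log2 of 1.01. Of 29 DNA replication genes 23 rose (26 adjusted over the list alone; camera adjusted p = 1.68e-24, adjusted p = 0.166 with an estimated correlation), such as Mcm4 (1.20), Rrm2 (1.16) and Cdc6 (1.10). Of 25 DNA repair genes 15 rose (18 adjusted over the list alone; camera adjusted p = 2.76e-11, adjusted p = 0.177 with an estimated correlation), and of the 14 histone genes 8 rose (9 adjusted over the list alone; camera adjusted p = 1.32e-09, adjusted p = 0.166 with an estimated correlation). Fancb (1.07), Blm (1.07), H1f5 (1.5) and H2ac20 (1.35) were members. Of 19 cholesterol synthesis genes 17 rose (18 adjusted over the list alone; camera adjusted p = 6.65e-21, adjusted p = 0.166 with an estimated correlation), such as Cyp51 (0.94), Insig1 (0.94), Pmvk (0.87) and Hmgcs1 (0.82). The fatty acid elongase Elovl6 (1.58) and the desaturase Fads2 (1.12) rose, in the fatty acid and phospholipid metabolism list with 6 of 32 genes higher and 7 lower, or 4 lower without KO sham 2 (9 and 8 adjusted over the list alone; camera adjusted p = 0.243). Tfrc, the transferrin receptor, rose by log2 1.60.

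Of 7 CXCR2 ligands 4 were higher in KO sham, also when adjusted over the list alone (camera adjusted p = 9.73e-05, adjusted p = 0.166 with an estimated correlation), such as Cxcl5 (1.39) and Cxcl1 (0.84). Of 23 NF-kB and inflammation genes 8 rose and 2 fell (12 and 3 adjusted over the list alone; camera adjusted p = 3.73e-04, adjusted p = 0.166 with an estimated correlation), such as Saa3 (0.82) and Il23a (-1.75). Without wt sham 2 or KO sham 1, 5 of them rose. Of 39 senescence-associated secretory genes 9 rose and 4 fell, also when adjusted over the list alone (camera adjusted p = 0.0266, adjusted p = 0.345 with an estimated correlation), such as Vegfa (-0.94). Without wt sham 2 that list's camera adjusted p was 0.0537, and without KO sham 3 it was 0.139. Of 37 cornified envelope genes 11 were lower (15 adjusted over the list alone; camera adjusted p = 1.88e-06, adjusted p = 0.441 with an estimated correlation), such as Klk7 (-1.03), Lor (-0.95), Rptn (-0.95) and Flg (-0.90). Their count was 7 without wt sham 2 and 7 without KO sham 3. Of 22 suprabasal genes 4 fell (6 adjusted over the list alone; camera adjusted p = 0.0108, adjusted p = 0.489 with an estimated correlation), such as the desmosomal cadherin Dsc1 (-1.59), and 2 fell without wt sham 2, wt sham 3, KO sham 1 or KO sham 3. In limma, 0 of 12 melanocyte, 0 of 18 hair follicle, 0 of 29 interferon and 0 of 26 ribosomal protein genes changed. In these 4 lists 0, 2, 3 and 2 members had an unadjusted p under 0.05, and neither camera (adjusted p = 0.627, 0.768, 0.956 and 0.284) nor fry (0.763, 0.941, 0.739 and 0.404) passed.

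Over all genes 2273 differed between the sham groups (10.2%), 1016 higher and 1257 lower in KO, of which 133 and 91 differed by at least 2-fold. The count was 1418 without wt sham 2, 1494 without KO sham 2, 976 from the 6 sham arrays alone and 797 with at least 1.5-fold.

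The genotypes were compared again under paraquat. Besides Atg7, late cornified envelope genes had the largest falls in KO. Lce1k fell by 1.87 ± 0.13 on the log2 scale (SE, n = 3 arrays per group, adjusted p = 3.25e-05) at dim signals of 50.3 ± 7.23 (SD) in wt and 13.7 ± 0.577 in KO. Lce1f, at 903 ± 104 in wt and 345 ± 87.5 in KO, was 2.67-fold lower (log2 -1.42 ± 0.16, adjusted p = 0.00186). Lce1b (-1.37), Lce1a1 (-1.27), Lce1a2 (-1.18) and the epidermal gene Prr9 (-1.20) fell, as did the ubiquitin ligase genes Lnx1 (-1.26) and Rnf223 (-1.20) and the phosphatase gene Acp7 (-1.17). Higher in KO were Ccr3 (1.44), Prl2c5 (1.11), Acta2 (0.99), Ulbp1 (0.90), Fyb (0.74) and Zdhhc2 (0.67). Mean signals of Fyb (16.7 in wt, 27.7 in KO) and Zdhhc2 (26 and 41.3) lay under every array median in both genotypes. Those of Ulbp1 in wt (40.7) and of Lce1a1 in KO (24.3) did so too. The gap junction gene Gjb2 (0.65), Papss1 (0.57), Grip1 (0.57) and the clock-linked repressor Bhlhe40 (0.57) were also higher. Papss1, Grip1 and Bhlhe40 lay under 1.5-fold. Adjusted over every probe set, these, Ccr3, Ulbp1, Gjb2, Lce1b, Lce1a2, Prr9 and Rnf223 missed the threshold.

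Of 37 cornified envelope genes 8 were lower in KO under paraquat (26 adjusted over the list alone), with a median log2 of -0.65. The camera adjusted p was 2.73e-29, and adjusted p = 0.166 with an estimated correlation. Flg, the filaggrin gene, was among them (-0.98). The mean log2 signal over this list was 9.79 to 9.96 in wt paraquat and 9.32, 9.30 and 8.94 in KO paraquat, the last in KO paraquat 3, which stood apart. The count of 8 was 3 without KO paraquat 3, 3 without wt paraquat 1 or 2, 5 without KO paraquat 1 and 4 without KO paraquat 2, and the median without KO paraquat 3 was -0.48. Of 22 suprabasal genes 3 were lower, namely Dsc1 (-0.93), Elf3 (-0.73) and Ppl (-0.51), and 12 adjusted over the list alone (camera adjusted p = 2.99e-09, adjusted p = 0.166 with an estimated correlation). No suprabasal gene passed singly without wt paraquat 1, wt paraquat 2, KO paraquat 1 or KO paraquat 3, and the list median without the last was -0.23 (camera adjusted p = 4.99e-07). Of 12 wound and stress genes Il1f8 (-0.88) and Il1f9 (-0.75) were lower (2 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.351). Dsc1, Elf3, Ppl, Il1f8 and Il1f9 missed the threshold when adjusted over every probe set.

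Among lists with 0 single members past limma's threshold between genotypes under paraquat, some passed camera at the preset correlation. None of them passed with an estimated correlation. The 31 mitosis genes had a median log2 of 0.34 (1 member adjusted over the list alone, 5 at an unadjusted p under 0.05; camera adjusted p = 2.55e-07, adjusted p = 0.547 with an estimated correlation, fry 0.356). KO paraquat 3 had a mean log2 of 7.36 over this list, against 7.01 and 7.01 in the other KO paraquat arrays. Without it the mitosis median was 0.20 (camera adjusted p = 5.44e-04). The fit shares 1 spread per gene over the 4 groups. The SD of the mitosis mean was 0.631 in wt sham, 0.0723 in wt paraquat and 0.205 in KO paraquat. The shared spread may thus be too wide here and too narrow in sham. Without wt sham 2 the mitosis median was 0.34, with 1 member past limma's threshold (camera adjusted p = 3.64e-14). The 19 cholesterol synthesis genes had a median of 0.21, with 0 members adjusted over the list alone and 7 at an unadjusted p under 0.05 (camera adjusted p = 1.88e-07, adjusted p = 0.345 with an estimated correlation, fry 0.0999). The 7 CXCR2 ligands had a median of 0.37 (3 adjusted over the list alone, 4 at an unadjusted p under 0.05; camera adjusted p = 0.00609, adjusted p = 0.202 with an estimated correlation, fry 0.0347), with Cxcl5 at 0.56 and Cxcl2 at 0.48. The 34 ATF4 targets had a median of 0.06, with 0 members adjusted over the list alone and 5 at an unadjusted p under 0.05, and passed neither camera (adjusted p = 0.489) nor fry (0.826). Without wt paraquat 2 the median of this list (ATF4 integrated stress response) was 0.04. Mean log2 signals over the leukocyte markers were 5.371 to 5.415 in KO paraquat and 5.416 to 5.479 in wt paraquat. Those over the fibroblast markers were 5.360 to 5.383 and 5.387 to 5.465. At an unadjusted p under 0.05, 0 leukocyte markers were higher and 3 lower, and 1 fibroblast marker was higher and 3 lower. For melanocyte, endothelial and hair follicle markers 0, 1 and 1 were higher and 2, 1 and 2 lower. Over all genes 122 differed (0.55%), 22 higher and 100 lower in KO. The count was 30 without wt paraquat 1, 38 without wt paraquat 2, 53 without KO paraquat 2 and 35 without KO paraquat 3. The higher genes alone numbered 43 without wt sham 2 and 11 without wt paraquat 3. The count was 3 from the 6 paraquat arrays alone, 44 without wt sham 2 and KO paraquat 3, 53 when every probe set was tested, and 223 to 249 with a variance trend, a filter on dim genes, 16 added or array weights.

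Whether the paraquat response itself differed by genotype was tested as the KO response minus the wt response. Trib3, an ATF4 target, fell in wt from a mean signal of 605 ± 61.7 (SD) to 82 ± 5.29, but in KO lay at 130 ± 0.577 and 93.3 ± 8.02, a difference of responses of log2 2.40 ± 0.13 (SE, n = 3 arrays per group, adjusted p = 1.85e-06). Of the 34 ATF4 targets 25 differed in this direction (32 adjusted over the list alone; median log2 0.89, camera adjusted p = 2.81e-48, adjusted p = 0.127 with an estimated correlation). Acot2 (3.37), Slc7a3 (3.27), Niban1 (3.07), Aldh1l2 (2.70) and Pck2 (2.38) had the same direction. These genes and the ATF4 list stood high in wt sham alone. Their difference of responses, fall in wt and lower level in KO sham thus rest on the same 3 arrays. In the opposite direction were Clca3a2 (-2.59), Stfa3 (-2.51), Csta3 (-2.47), Cxcl3 (-2.19) and Il24 (-1.76). Mean signals in wt and KO sham were 36.7 and 182 for Clca3a2, 184 and 1224 for Stfa3 and 31.7 and 240 for Csta3. They were 24.7 and 140 for Cxcl3 and 279 and 1081 for Il24. Under paraquat the same pairs were 21 and 17, 1382 and 1628, 504 and 696, 443 and 585, and 2381 and 2725. These differences of responses thus rest mostly on the levels in sham. Of 31 mitosis genes 3 differed (28 adjusted over the list alone; median log2 -1.0, camera adjusted p = 1.03e-18, adjusted p = 0.306 with an estimated correlation), among them Bub1b (-1.56). The mitosis count was 21 without wt sham 1 and 4 without wt sham 2, and no member passed singly without any other array. Adjusted over every probe set, Bub1b missed the threshold. Gsta4 (-1.15) rose less in KO, and Fn1 (1.43) and Acta2 (1.10) fell less. Mean signals of Fn1 were 1984 in wt sham and 876 in KO sham, but 84.3 and 102 under paraquat. Its difference thus rests mostly on the starting level. Acta2 lay at 6942 and 6457 in sham and parted under paraquat (560 in wt, 1112 in KO). Gsta4 differed in sham (391 to 465 in wt, 677 to 898 in KO) and under paraquat (4722 to 4792 and 3739 to 4337).

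Over all genes 508 responses differed (2.29%), 309 in the positive and 199 in the negative direction. Of the 508, 437 also differed between genotypes in sham, 35 under paraquat, 4 in both and 40 in neither. The count was 280 without wt sham 3, 298 without KO sham 2, 250, 269 and 304 without wt paraquat 1, 2 and 3, and 333, 282 and 283 without KO paraquat 1, 2 and 3. It was 268 without wt sham 2 and KO paraquat 3, 297 when every probe set was tested, and 783, 894 and 882 with a variance trend, a filter on dim genes and 16 added. The share of positive differences, 60.8%, was 70.6% with centring on the array median (394 positive, 164 negative), 71.4% over every probe set and 55.1% to 74.8% without 1 array. The negative count alone was 314 without wt sham 1, 100 without KO sham 1 and 119 without KO sham 3.

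Across genes the paraquat responses of wt and KO ran in parallel, as 2329 genes rose in both (480 in independent lists of these sizes) and 1951 fell in both (400 in independent lists), while 41 changed in opposite directions. The log2 changes had Pearson r = 0.827, Spearman rho = 0.656 and an orthogonal slope of KO on wt of 0.877, across genes, which are not independent replicates. Of 1438 genes called and changed at least 2-fold in either genotype, such as Fn1, Lce3a and Psca, 955 changed more in wt and 483 more in KO, and 1409 had the same sign. The genotype differences in sham and under paraquat were less alike across genes (r = 0.245, rho = 0.164), with 14 genes higher in both (1.01 in independent lists), 21 lower in both (5.67) and 3 opposite.

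**Figure D4:**
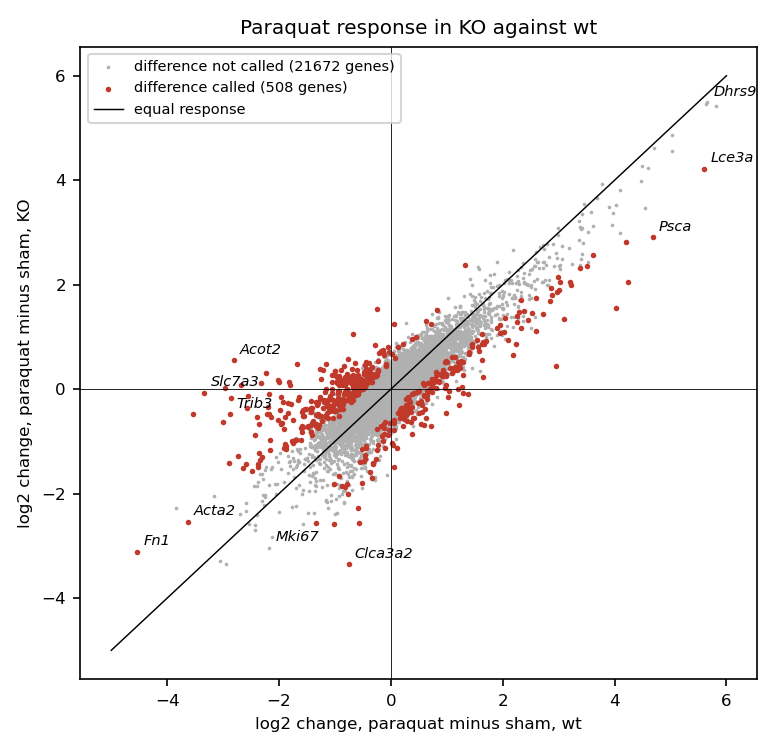
Log2 change under paraquat in KO (vertical axis) against that in wt (horizontal axis), 1 point per gene over 22180 genes. The line marks equal responses, and the 508 red genes passed the test of the difference. Acot2, Slc7a3 and Trib3 lie above the line, with differences of 3.37, 3.27 and 2.40, and Clca3a2 below it, with -2.59.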

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

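The tests of explanations here, and the counts over regrouped arrays, were chosen after the results were seen, while the tests of each gene's and each list's difference between responses were planned. In the values that follow, a gene's or list's response to paraquat in KO minus that in wt is given in log2, and each passed limma's test or camera's test of that difference.

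The responses of 508 genes differed by genotype. Positive differences were Acot2 3.37, Slc7a3 3.27, Niban1 3.07, B4galnt2 2.98, Car6 2.77, Aldh1l2 2.70, Fam171b 2.54, Reep6 2.43, Heg1 2.41, Trib3 2.40 and Pck2 2.38. Smaller positive differences were Mmp13 1.79, Slc7a5 1.75, Slc7a11 1.73, Mthfd2 1.57, Fn1 1.43, Acta2 1.10, Sqstm1 1.09 and Ulk2 0.97. Negative differences were Clca3a2 -2.59, Stfa3 -2.51, Csta3 -2.47, Cxcl3 -2.19, Depdc1a -2.0, Psca -1.78, Il24 -1.76, Bub1b -1.56, Knl1 -1.56, Stfa1 -1.53, Tfrc -1.43, Elovl6 -1.29, Gsta4 -1.15, Il1f9 -1.14, Lce1f -1.10, Cdc6 -1.03, Cxcl5 -0.83, Cyp51 -0.79 and Cxcl1 -0.60. Adjusted over every probe set, Car6, Depdc1a, Bub1b, Knl1, Stfa1, Elovl6, Lce1f, Cxcl5, Cyp51 and Cxcl1 missed the threshold. List medians were 0.89 for ATF4 targets, 0.14 for matrix genes, 0.14 for ribosomal proteins, -0.21 for the cornified envelope, -0.27 for NF-kB genes, -0.28 for CXCR2 ligands and -0.29 for wound and stress keratins. They were -0.42 for histones, -0.43 for DNA repair, -0.44 for cholesterol synthesis, -0.59 for DNA replication and -1.0 for mitosis, and each of these 12 lists lost its call with an estimated correlation. Left-out arrays ended 4 of these list calls. The adjusted p of the cornified envelope and barrier list was 0.0776 without wt sham 1, 0.0788 without KO sham 1 and 0.106 without KO paraquat 3. That of the list of wound and stress keratins was 0.0542 to 0.114 without wt sham 1 or 3, KO sham 1 or 2, wt paraquat 3 or KO paraquat 3. The extracellular matrix and TGF-beta response list stood at 0.101 without wt sham 1, and ribosomal proteins at 0.0537 without wt sham 2. Medians moved by over 1.5 times for the cornified envelope and barrier (-0.12 without wt sham 1, -0.33 without wt sham 2, -0.08 without KO paraquat 3), DNA repair (-0.25 without wt sham 2) and CXCR2 ligands (-0.43 without wt sham 1, -0.42 without KO sham 2). They did so too for wound and stress keratins (-0.19 without KO paraquat 3), extracellular matrix and TGF-beta response (0.09 without wt sham 1) and ribosomal proteins (0.09 without wt sham 2).

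A random sample of the possible regroupings of the genotype labels within treatments was run beside the real one, 100 in all. In 5 of these 100, the real one included, at least 508 genes passed. The counts that follow cover this sample only. The highest of the others, with 1813 genes, kept the sham labels and exchanged all labels under paraquat. The 8 others that left the sham genotype labels as they were, the 4 with as many genes among them, gave 316 to 1813 and carried the genotype difference in sham, so the count of 5 was set by that difference and does not decide whether chance can be excluded. The 91 that broke up the sham labels gave at most 14. Such mixing adds the sham genotype difference to the residual spread, which lowers these counts whatever the responses. They are thus no chance level for the 508. Exchanging all labels under paraquat turns the test into that of the genotype difference averaged over both treatments. For the 4 pairwise comparisons 3 against 3 arrays make 10 splits, too few for a share under 0.05. In each, 1 of 10 splits, the real one, gave as many genes, with 6480, 6017, 2273 and 122 genes in the real split and 1, 0, 0 and 0 in the highest other. Every other split mixes the groups compared, which lowers its count in the same way.

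Probe sets with no single gene in the annotation lie outside the gene tests. Of 17824 such probe sets 1964 changed under paraquat in wt and 2207 in KO, by limma fitted to every probe set and adjusted over these 17824 alone.

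ATF4 targets were higher in wt sham than in KO sham. A single wt sham array is argued against, since the list median stayed at or below -0.821 (log2, KO minus wt) whichever wt sham array was left out. Low proliferation of the wt sham cultures could go with it: 6 of 6 paraquat arrays had low mitosis means without high ATF4 means, but they received another treatment, and the wt sham array with the lowest mitosis mean had the highest ATF4 mean, so this stays open. Separate handling of the wt sham cultures cannot be told apart from genotype, because the series holds 1 set of them. Their mean ATF4 level lay 1.10 above the highest other group. The same limit holds for the fall of this list under paraquat in wt and for its difference between responses. An effect of Atg7 loss remains a hypothesis beside low proliferation, separate handling and the stress of the endoplasmic reticulum weighed at the end.

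Proliferation genes were higher in KO sham than in wt sham. Wt sham 2 alone is argued against, since the mitosis median was 1.01 without it with all 31 members called. A different growth state at harvest could still account for it and cannot be told apart from genotype here. The range of the mitosis mean within wt sham (1.23) was 0.914 of the difference between the genotypes (1.35), but without wt sham 2 it was 0.391 against 1.00, or 0.389 of the difference. A genotype effect on cell division also stays open.

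The cornified envelope list had a lower median in KO than in wt under paraquat, while few of its 37 genes passed singly. Without KO paraquat 3 the count was 3, and the list's call was lost with an estimated correlation. KO paraquat 3 alone is argued against, since the list median was at or below -0.48 whichever KO paraquat array was left out. A response that was smaller on average across genes in KO may account for the difference in response. The observed mean (-0.283) departed by 0.00220 ± 0.0642 (SE over members) from that predicted (-0.286) by the slope over 22092 other genes (0.876). A smaller response was not general, as the mitosis and DNA replication lists fell more in KO. Their median differences between responses were -1.0 and -0.59. The slope pools such genes with those that responded less. An earlier form of the test used the slope over 1108 genes picked by their change in wt (0.738), and such picking alone lowers the slope. It predicted a larger deficit than was seen (departure 0.322 ± 0.0779), and because of the picking this departure decides nothing. Members of a list can move together, so both SE over members may be too small. The share due to a smaller response in KO is open. A lower level before treatment may contribute, with a list median of -0.390 in sham against -0.651 under paraquat, and cannot be told apart from a genotype effect on differentiation.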

How the results depend on the processing

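The alternatives with 16 added, without both arrays that stood apart, and with the list rescalings were chosen after seeing the data. No called gene result turned its sign under any alternative run, and no list did that passed both there and in the main test. Lists that lost their call were not compared for sign. The fold limit, the 6-array fits, the variance trend, the replicate blocks and the test of every probe set leave a gene's log2 as it was. Those settings could not turn the sign of a gene. The cause of each move was not tested except where fewer arrays or a fold limit make it. With at least 1.5-fold, 2999 genes changed in wt, 2570 in KO and 797 between sham groups. From only the 6 arrays of the groups compared, 976 genes differed in sham and 3 under paraquat, and Atg7 under paraquat lost its call. This setting cannot change its log2 of -1.87; the SE was 0.15 in place of 0.13, the degrees of freedom 6.59 in place of 12.98, and the unadjusted p 9.24e-06 in place of 3.69e-09. Its adjusted p was 0.0512, the highest over its 24 alternatives, against a lowest of 9.94e-06. Without wt sham 2 and KO paraquat 3, the counts were 1360 in sham, 44 under paraquat and 268 for the difference between responses. Under paraquat, KO against wt gave 228 with a filter on dim genes, 223 with a variance trend, 249 with array weights, 231 with 16 added and 53 over every probe set. The difference between responses gave 894 with that filter, 783 with the trend, 882 with 16 added and 297 over every probe set. With an estimated correlation 0 lists passed camera, against 83 at the preset correlation, with 38 at an unadjusted p under 0.05 and 71 passing fry. Leaving out 1 array gave 5583 to 6470 genes for paraquat in wt, 4988 to 6216 in KO, 1418 to 2363 for KO against wt in sham, 30 to 171 under paraquat, 250 to 700 for the difference between responses, and 79 to 83 lists. The same fits gave Pearson r from 0.793 to 0.849, slopes from 0.844 to 0.923, and Atg7 from -1.60 to -1.45 in sham and -2.01 to -1.69 under paraquat. The replicate number as a block gave 6250, 5805, 2014, 117 and 439 genes over all groups, and within genotype a correlation of -0.0148. Correlations between like-numbered arrays after removing group means ran from -0.142 to 0.105 and were the highest match in 7 of 18 pairs. All 3 pairs of KO sham with KO paraquat were among these (0.0481, 0.0937 and 0.105), so pairing within KO stays open. Of 490 called gene results, 59 lost their call without both arrays, 63 of the 420 with such a fit from 6 arrays, 82 with at least 1.5-fold and 66 over every probe set (32 of them for the difference between responses, 16 for KO against wt under paraquat). The dim filter left 15 of them untested, and the other alternatives that keep every array ended 23 or fewer calls each. Dim signals, where rounding is coarse, limit what the arrays resolve.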

Other observations

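The test of the hypothesis in this part was chosen after the results were seen. Several lists in KO under paraquat are not described above. Of 21 genes of the unfolded protein response of the endoplasmic reticulum 10 fell and 2 rose (11 and 3 adjusted over the list alone; camera adjusted p = 0.00161, adjusted p = 0.166 with an estimated correlation), such as the chaperones Dnajc3 (-0.89), Pdia6 (-0.83) and Hsp90b1 (-0.82). Of 17 basal keratinocyte genes 7 fell and 1 rose (7 and 2 adjusted over the list alone; camera adjusted p = 0.0215, adjusted p = 0.572 with an estimated correlation), such as Col7a1 (-2.07) and Lamb3 (-1.05). Without KO sham 3 the camera adjusted p of the basal list was 0.0549. Lipid genes went both ways: of 32 fatty acid and phospholipid genes 8 rose and 12 fell (9 and 14 adjusted over the list alone; camera adjusted p = 0.397), with rises in Dgat2 (2.34) and Agpat2 (1.42), which make glycerolipids, and in the lipase Lipe (1.44), and a fall in the elongase Elovl5 (-0.81). Of 25 genes of oxidised lipids and prostaglandins 9 rose and 4 fell (10 and 5 adjusted over the list alone; camera adjusted p = 0.179), such as Aloxe3 (2.96) and Ptges (1.70). Of 12 endothelial markers 3 rose and 1 fell, also when adjusted over the list alone (camera adjusted p = 0.141), such as Kdr (1.38) and Flt1 (-0.69).

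A hypothesis was stress of the endoplasmic reticulum in the wt sham cultures as the source of their higher ATF4 targets, which would lower the unfolded protein response list in KO. Its median was 0.120 (quartiles -0.0780 and 0.251, 9 of 21 members below 0). This argues against a higher level of the list as a whole in wt sham. Members went both ways, with 7 higher and 5 lower in KO sham at an unadjusted p under 0.05 in limma. The chaperone gene Hspa5 lay at 1674 to 2032 in wt sham and 1530 to 1630 in KO sham. Stress acting through part of these genes, or on ATF4 without them, was not tested and stays open.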
